A study of Homo sapiens with 10 samples.

How the data were processed

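Bone marrow aspirate concentrate (BMAC) and cultured mesenchymal stromal cells (MSC) were profiled by droplet single-cell RNA sequencing. Per the labels' protocols, marrow was aspirated and concentrated with a commercial centrifugation device, red blood cells were lysed, and libraries were made with the Chromium Single Cell 3' v2 chemistry. The labels give 9 samples of BMAC and 1 sample of cultured MSC bought from a commercial supplier. They do not say whether the BMAC samples came from separate people, so p-values measure only the spread between these samples. Samples are called here by their group and a replicate number given in the order of the records, which pairs nothing. The letters of the library names split the BMAC samples into 6 (replicates 1 to 6, with the cultured library) and 3 (replicates 7 to 9). This was treated as a possible technical batch whose meaning the labels do not state.

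The values are counts deposited by the authors as 1 pooled matrix of unique molecular identifiers (UMIs) per gene and cell, 33694 genes in the rows and barcodes in the columns, with no normalization. Cell Ranger 2.2.0 and the GRCh38 build are named in the submitters' processing notes. The barcodes had already been called as cells before deposit. Whether libraries were brought to equal depth when they were pooled is not given in the sources used here. Each barcode carries a suffix, and the series design text ties each suffix to a library. A suffix with 673 barcodes belongs to no sample and was not used, which left 15851 barcodes. Gene symbols and Ensembl identifiers were taken as deposited. Positions came from GENCODE release 29 on GRCh38, which matched 33132 of the 33694 identifiers (98.33%) and may not be the annotation the authors used.

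Barcodes were kept with at least 200 genes and at most 20% mitochondrial counts. Of 12850 BMAC barcodes, 1397 held fewer than 200 genes, of which 645 came from replicate 7 and 570 from replicate 9, and 93.0% to 96.1% of the counts in them were haemoglobin transcripts. Doublets were scored per library with Scrublet as implemented in scanpy (expected rate 5%). It called 34 barcodes over all libraries (0.236%), too few for a working caller. Those 34 were removed, doublets were treated as still present, and removal of the 5% of cells with the highest scores was tried as an alternative. After filtering, 11407 BMAC cells and 2996 cultured cells remained. A barcode sequence found in more than one library, as a swapped index would give, was carried by 264 of the BMAC cells and 53 of the cultured cells.

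BMAC cells were clustered without the cultured library. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen after removal of every gene of the 5 lists tested across classes and of mitochondrial, ribosomal, sex-linked, immunoglobulin and T-cell receptor genes. Then 30 principal components, 15 exact nearest neighbours and Leiden clustering at resolution 1 were used. A cluster was called X-like when at least 3 markers of type X were detected in at least 10% of its cells with a mean log2 fold of at least 1 over the other cells (pseudocount 5 CPM, where CPM is a gene's count over its total, scaled to a common sum). It stayed unnamed where another type led its top 10 genes, or tied there at 1 gene each, as in cluster 10. The marker lists were fixed before the data were examined, and the scoring rule was set afterwards. Because T and NK markers overlapped between clusters, T and NK clusters shared one name. The marker lists were erythroid, granulocyte precursor, neutrophil, monocyte, macrophage, conventional dendritic, plasmacytoid dendritic, T, NK, B, B precursor, plasma, haematopoietic stem and progenitor, megakaryocyte, eosinophil with basophil and mast, stromal, endothelial, osteoblast, adipocyte, smooth muscle with pericyte, and cell cycle.

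For the shares of cells meeting a marker definition of MSC, each cell was thinned to 1000 UMIs, because cultured cells held more UMIs than BMAC cells. No cell was shallower than that. A gene was positive at 1 UMI or more and negative at 0. Shares have exact Clopper-Pearson 95% intervals. For a share of 0, the limit given is that of 3 counts, and it limits the share of cells in which the genes are detected, not the share that express them. Shares of each definition were compared with the collagen-based definition over the 9 BMAC libraries by a two-sided exact sign-flip permutation test with Benjamini-Hochberg adjustment over 8 definitions. Class shares of the 6 and 3 BMAC libraries were compared by a two-sided exact permutation test over 84 splits.

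For cultured MSC against BMAC, counts were summed per library and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) after filterByExpr and TMM normalization, with thresholds of an adjusted p under 0.05 and an absolute log2 fold change over 1. There was 1 cultured library, so the spread came from the BMAC libraries and the cultured library was assumed to vary like them. The p-values therefore compare this library with BMAC, not culture in general. Lists were tested with camera (limma 3.58.1) on log-CPM with prior count 2, with a preset correlation of 0.01 and with an estimated one. Counts "adjusted over the list alone" use p-values adjusted over the list's own genes. Folds against a group with no count use a floor of 3 counts over the whole group. For list genes across BMAC classes, counts were summed per library and class where a class had at least 10 cells in at least 3 libraries. One edgeR fit with the library as a block compared each class with the mean of the other classes on the log scale, at an adjusted p under 0.05. Classes with almost no counts pull that mean down, so a gene may be called higher at a CPM below the others' average. The CPM given per class are not TMM-scaled, which can have the same effect. Unnamed clusters were not in this fit. For the few stromal-like BMAC cells against cultured MSC, ratios of CPM are given with exact binomial counting intervals, which leave out the spread between libraries. The same edgeR test on sums per library (4 BMAC libraries, with the cultured library assumed to vary like them) was added after the data were seen, and 302 genes passed its filter. List medians there are placed among 10000 random lists of the same size matched on mean CPM in 20 bins, over genes with a mean CPM above 25. Intervals and floors cover counting error only. In the tables, 756 sex-linked, immunoglobulin, T-cell receptor and copy-variable HLA genes were left out.

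Lists fixed for cultured MSC against BMAC were consensus MSC surface positive, consensus MSC surface negative, other MSC surface markers, marrow niche genes, extracellular matrix, contractile cytoskeleton, osteogenic, adipogenic, chondrogenic, proliferation, senescence and p53 targets, glycolysis, MHC class II and immediate early stress. The 5 lists also tested across classes were growth factors, pro-inflammatory cytokines, anti-inflammatory factors, chemokines, and matrix proteases and inhibitors. The marker lists, the gene lists, the thresholds, the rule for named genes and the tests of the report were chosen before the data were examined, except the edgeR test of the stromal-like cells. Tests in the closing part that came later are named there. That rule took the 10 genes higher and the 10 lower with the largest fold change among those with at least 50 CPM in the higher group and detected in every library of it, 2 genes per list, and 8 genes named in advance (NT5E, THY1, ENG, PTPRC, CD34, CD14, LEPR, CXCL12). Across classes it took up to 4 pairs of gene and class per list with at least 10 CPM, and IL1RN, IL1B, TGFB1, VEGFA, IGF1, MMP9 and TIMP1 always. For the stromal-like cells it took the 8 highest and 8 lowest ratios with at least 30 UMIs in the higher sum. A few of the genes this rule took, and 1 marker definition, are not reported here.

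The edgeR fits and the counting intervals were tested on simulated data, the fit across classes for 1 class only, while camera, the exact permutation tests and the random lists were not. For cultured MSC against BMAC, 96% of genes made 4-fold higher and 86% of those made 4-fold lower were called, as were 100% of those made 16-fold higher and 96% of those made 16-fold lower, with 14 false calls among 10336 genes. That simulation changed 50 genes per fold and direction, whereas the real comparison called 47.5% of the genes tested. How the fit performs when so many genes change was not tested. For the monocyte-like class against the others, 100% of the changed genes that passed the filter again were called, with 8 false calls among 4547 genes. These were 43 genes made 2-fold higher, 50 made 4-fold higher, 43 made 2-fold lower and 39 made 4-fold lower. Changed genes that the filter removed were not scored. For the stromal-like cells against cultured MSC, 20 draws were made from the 302 genes, and only genes that passed the filter again were scored. Of these, edgeR called 0% of 172 made 4-fold higher and 2.04% of 196 made 16-fold higher. It called 6.38% of 47 made 4-fold lower and 29.6% of 54 made 16-fold lower, with 3 false calls among 2268 unchanged genes. Here 40 genes were changed per draw, and no result with most of the tested genes changed is given. The edgeR test of the stromal-like cells therefore misses most changes, and a gene it does not call may still differ. The counting intervals held the true ratio for 94.0% to 98.0% of genes. Counts varied by counting error only in that simulation, so it does not test how the intervals do with a spread between cells or libraries. As a further check, each BMAC library in turn was set alone against all other libraries, the cultured one included, and 0 genes were called each time. The cultured library widens the spread among the others, so 0 calls were likely in any case and say little about false calls. Among the BMAC libraries only, the same check called 0 genes for 8 libraries and 1 gene for replicate 8. Alternatives were DESeq2 (1.42.0), DESeq2 size factors within edgeR, no filter on low counts, other clustering settings, other thinning depths, fits without the library block, the 6 libraries of one possible batch alone, and each BMAC library left out. Analysis used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9 and scikit-learn 1.9.0, with figures from matplotlib 3.10.9.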

Results

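Bone marrow aspirate concentrate (BMAC) is a cell suspension made by centrifuging aspirated marrow. The series set 9 libraries of clinical-grade BMAC beside 1 library of culture-grown mesenchymal stromal cells (MSC), the adherent fibroblast-like cells of marrow stroma. The BMAC libraries held 603 to 1951 cells after filtering, 11407 in all, with library totals of 3784208 to 14446952 UMIs. Their median cell held 2774 to 5075 UMIs depending on the library. The cultured library held 2996 cells and 52518181 UMIs, with a median of 16025 UMIs and 3450 genes per cell, against 3959 UMIs and 1081 genes over all BMAC cells. Shares of cells with a UMI therefore rest on very different depths in the 2 groups, and such shares are given at equal depth, with full depth beside it where named.

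The first question was what the concentrate contains. Lymphocytes formed the largest class of the deposited cells left after filtering: T and NK-like cells made up 40.05% ± 10.9 (SD, n = 9 libraries) of BMAC cells. Erythroid-like cells, the haemoglobin-producing red cell precursors, made up 16.5% ± 12 and monocyte-like cells 10.75% ± 7.07. Haematopoietic stem and progenitor-like cells, led by SPINK2, AVP, CRHBP and CD34, made up 4.30% ± 2.24. B-like cells followed with 3.93% ± 1.46, B precursor-like cells with 3.24% ± 1.80, conventional dendritic-like cells with 2.89% ± 2.09, plasmacytoid dendritic-like cells with 2.06% ± 1.47, granulocyte precursor-like cells with 1.69% ± 1.16 and plasma-like cells with 1.30% ± 0.954. No cluster met the marker rule for neutrophil, macrophage, megakaryocyte, eosinophil with basophil and mast, endothelial, osteoblast, adipocyte, smooth muscle or stromal cells. The fewest UMIs in a deposited barcode ran from 1748 in replicate 8 to 3363 in replicate 2. Cells with less RNA are therefore missing from these shares, and a missing class does not show that the concentrate lacks those cells.

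The libraries differed widely in these shares. T and NK-like cells ranged from 16.9% in replicate 7 to 55.2% in replicate 8. Erythroid-like cells ranged from 1.87% in replicate 6 to 33.1% in replicate 7, and monocyte-like cells from 3.08% in replicate 7 to 22.8% in replicate 6. Red cells had been lysed before loading and barcodes under 200 genes were removed, so the erythroid share is that of the cells left after both steps. Of 26 clusters, 5 stayed unnamed and held 13.25% ± 6.99 of the cells (6.64% to 29.5%). Cluster 5, led by FAM178B, KCNH2, NMU and EPCAM, held 5.08% ± 2.77 of cells. Cluster 10, led by RETN, MPO, LYZ and RNASE2, held 3.67% ± 1.91. It had 6 granulocyte precursor markers with a mean log2 fold of 1.83. In its top 10 genes this type and another tied at 1 marker each, so it stayed unnamed. Cluster 13, led by ITGA2B, TPSB2, TPSAB1, GATA2 and IL1B, held 2.40% ± 1.70. Cluster 16, led by AK1, AKR1C3, HBQ1 and PRDX2, held 1.44% ± 1.74. Cluster 24 mixed red cell and T cell genes (KRT1, GZMK, HBB, HBA2, LTB), and 90.1% of its 111 cells came from replicate 7. Between the 6 and the 3 BMAC libraries whose names carry different letters, no class share passed adjustment over 15 classes (two-sided exact permutation test over 84 splits). A single class could not have passed at any difference, so this does not show that the shares were equal. Cluster 16 had means of 0.646% and 3.02% (exact permutation p = 0.0119, the smallest these splits can give, adjusted p = 0.179). The second mean rests much on replicate 7 (5.84%), with 2.03% in replicate 8 and 1.18% in replicate 9. The share of granulocyte precursor-like cells rested on the clustering and on leaving cluster 10 unnamed, and rose to 5.36% at resolution 0.5.

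**Figure D1:**
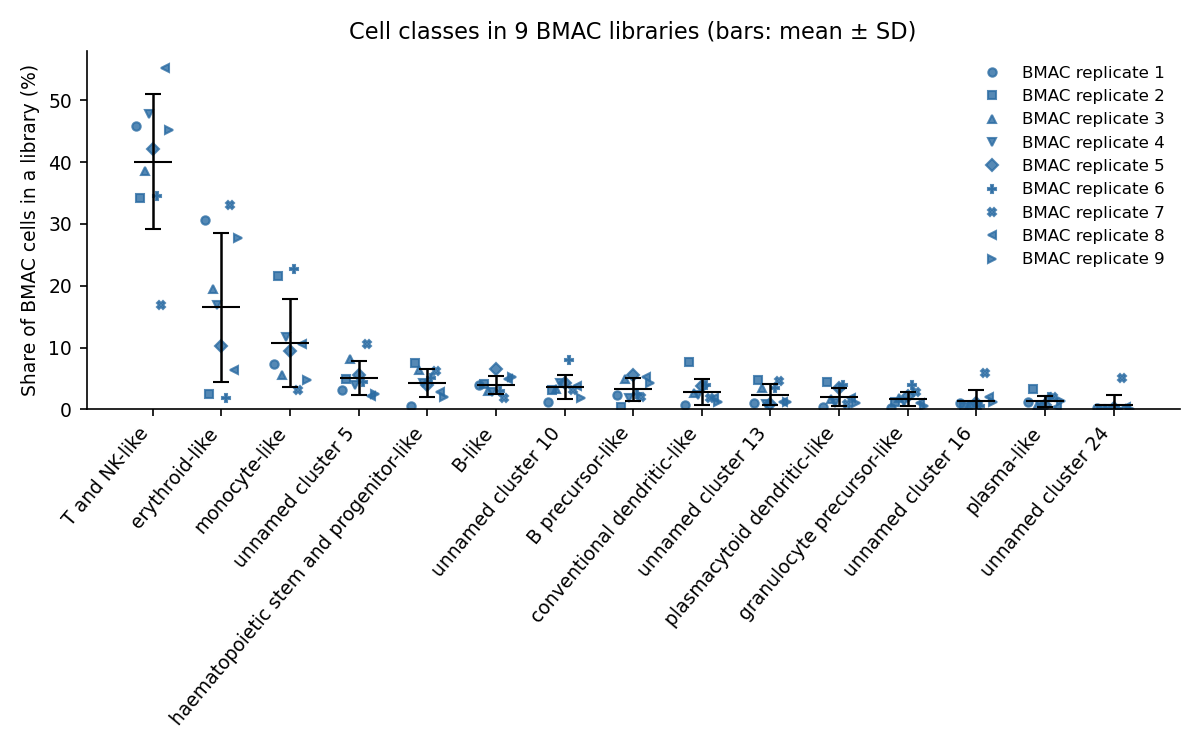
Share of BMAC cells (%, y axis) in each cell class or unnamed cluster (x axis), with 1 point per library and bars at the mean ± SD of 9 libraries. T and NK-like cells were the largest class (40.05% ± 10.9), and erythroid-like cells had the largest SD between libraries (16.5% ± 12, from 1.87% to 33.1%).

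The second question was how many BMAC cells meet the marker definitions in use for MSC. Cells carrying the standard surface triple were not seen. NT5E (CD73, the enzyme that makes adenosine from AMP, chromosome 6, 85449584 to 85495791, plus strand), THY1 (CD90, chromosome 11, 119417378 to 119424985, minus strand) and ENG (CD105, a co-receptor for TGF-beta, chromosome 9, 127815012 to 127854756, minus strand) were detected together in 0 of 11407 BMAC cells, which allows a detected share of up to 0.0263% at this depth and does not limit the share of cells that express them. At the same depth of 1000 UMIs per cell, 0.768% of cultured cells carried all 3 (Clopper-Pearson 95% interval 0.487% to 1.15%), so the triple itself was rarely seen at this depth. At full depth the cultured share was 52.9% and the BMAC count was still 0, though BMAC cells held far fewer UMIs each.

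Definitions built on other markers named other cells. LEPR, the leptin receptor that marks perivascular marrow stroma (chromosome 1, 65420652 to 65641559, plus strand), without the pan-leukocyte marker PTPRC (CD45, chromosome 1, 198638457 to 198757476, plus strand), was met by 44 BMAC cells, 0.363% ± 0.152 per library (n = 9), and by 4.17% of cultured cells. LEPR with CXCL12, the chemokine that holds haematopoietic stem cells in the marrow (chromosome 10, 44370165 to 44386493, minus strand), was met by 5 BMAC cells (0.0392% ± 0.0487) and 1.44% of cultured cells. NGFR without PTPRC was met by 4 cells (0.0347% ± 0.0598) and 0.0668% of cultured cells. MCAM without PTPRC was met by 2 cells (0.0157% ± 0.0319) and 1.84% of cultured cells. PDGFRA or PDGFRB without PTPRC was met by 5 cells (0.0501% ± 0.0570) and 20.2% of cultured cells. THY1 with VCAM1 and without PTPRC was met by 0 cells, which allows a detected share of up to 0.0263%, and by 3.71% of cultured cells. At least 2 of the matrix genes COL1A1, COL1A2, COL3A1, DCN and LUM without PTPRC were found in 4 cells (0.0328% ± 0.0497) and in 96.9% of cultured cells. This collagen definition was the one nearly every cultured cell met at low depth.

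Without thinning, the LEPR definition took 255 BMAC cells (2.08% ± 1.05), NGFR 17 (0.162% ± 0.188), PDGFRA or PDGFRB 11 (0.106% ± 0.0838), LEPR with CXCL12 8 (0.0626% ± 0.0895), the collagen definition 7 (0.0606% ± 0.0960), MCAM 5 (0.0441% ± 0.0737) and THY1 with VCAM1 1 cell (0.00644% ± 0.0193). The cultured shares were then 33.9% for LEPR, 0.634% for NGFR, 92.5% for PDGFRA or PDGFRB, 31.6% for LEPR with CXCL12, 99.97% for collagen, 20.6% for MCAM and 68.4% for THY1 with VCAM1. Over all definitions 283 BMAC cells met at least 1, and 275 of these met exactly 1. The LEPR and collagen definitions shared 6 cells. LEPR with CXCL12 and the collagen definition also shared 6, which was 66.7% of the 9 cells in either.

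The classes that held these cells differed by definition. Of the 255 cells with LEPR and without PTPRC, 165 (64.7%) lay in cluster 5, 36 in erythroid-like cells, 14 in cluster 13, 14 in cluster 16 and 6 in the plasma-like cluster. Of the 17 cells with NGFR, 9 were plasmacytoid dendritic-like. The plasma-like cluster held 6 of the 7 collagen-defined cells, and the last one was an erythroid-like cell with 86.5% haemoglobin counts. As background, at 1000 UMIs LEPR was seen in 0.114% of T and NK-like cells (median 3346 UMIs), against 3.28% of cluster 5 (median 16784 UMIs). At full depth these shares were 0.342% and 32.4%. In the same T and NK-like cells CXCL12 was seen in 0.0456%, PDGFRB in 0.0911%, VCAM1 and COL1A1 in 0.0228% each and ENG in 0.683%. NGFR, PDGFRA and COL1A2 were seen in 0, which allows up to 0.0683%. In monocyte-like cells (median 3874 UMIs) NT5E, THY1 and MCAM were at 0, which allows up to 0.242%. NT5E was highest in B-like cells (2.80% thinned, 10.1% at full depth, 30.6 CPM). The share of BMAC cells with PDGFRA or PDGFRB lay at or below the PDGFRB background, and the LEPR share lay above its own. Of the 5 cells with PDGFRA or PDGFRB, 2 also met the collagen definition (0.00175 expected if independent), so background may not account for all of them. The NGFR and MCAM shares were not above the limits that a count of 0 in 1 class allows, so at this depth they could not be told from background, which does not exclude expression in few cells.

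The LEPR share exceeded the collagen share in 8 of 9 BMAC libraries, by a mean of 0.330 percentage points (two-sided exact sign-flip permutation test, p = 0.00781, adjusted p = 0.0625 over 8 definitions), which fails the correction. At full depth it was higher in 9 of 9, by 2.02 points (exact permutation p = 0.00391, the smallest this test can give, adjusted p = 0.0312). For the other definitions adjusted p-values were 0.50 or more at 1000 UMIs in this exact test. Many libraries held no cell of either definition there, and differences of 0 left too few sign flips for any of them to pass. These p-values do not show that the shares were equal. The call for LEPR depended on depth, and the absence of PTPRC is weak evidence at low depth. Its absence also does not set stroma apart from erythroid-like cells, of which 2.54% had a PTPRC UMI at full depth.

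**Figure D2:**
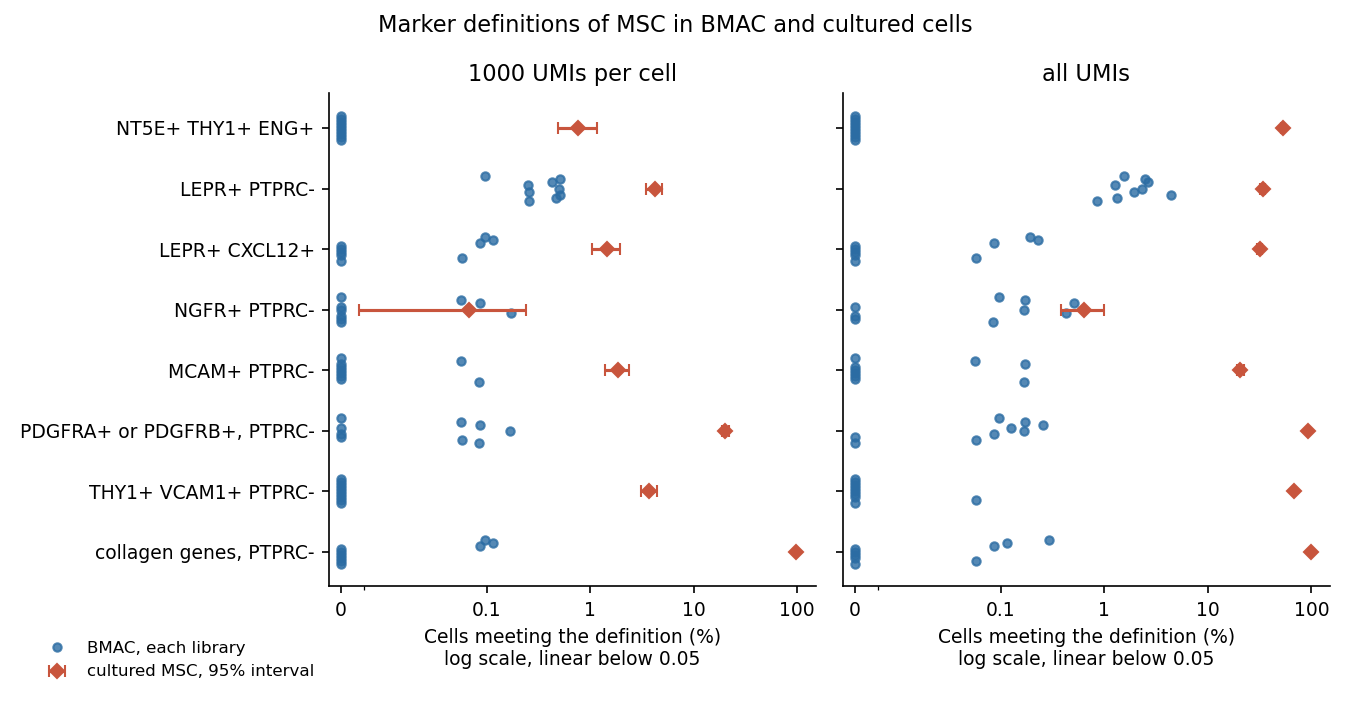
Share of cells (%, x axis, logarithmic above 0.05 and linear below) meeting each of 8 marker definitions of MSC (y axis), with 1 circle per BMAC library and a diamond with its 95% interval for the cultured library, at 1000 UMIs per cell (left) and with all UMIs (right). The collagen definition took 96.9% of cultured cells and 0.0328% ± 0.0497 of BMAC cells when thinned.

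The third question was how cultured MSC differ from the whole concentrate in expression. Cultured MSC were set apart by matrix genes: COL1A1, the main fibrillar collagen chain (ENSG00000108821, chromosome 17, 50183289 to 50201632, minus strand), stood at 5114 CPM against 0.217 ± 0.293 CPM in BMAC (SD, n = 9), a log2 fold change of 14.20 (SE 0.501, edgeR adjusted p = 1.05e-10). COL12A1, a fibril-associated collagen, was at 799 CPM with no count in any BMAC library, at least 18020-fold higher. Conversely, the lymphocyte surface gene CD52 was at 481 ± 172 CPM in BMAC and had no count in the cultured library, at least 8124-fold lower. PTPRC was at 173 ± 63.0 CPM in BMAC and had 1 count in cultured MSC, a ratio of 8904-fold (95% counting interval 1598 to 351700). In edgeR's quasi-likelihood test 3708 genes were higher and 3354 lower in the cultured library, 47.5% of the 14854 tested. BMAC is a mixture and the cultured library a single source with no replicate, so these calls set this library against the mixture. A gene can rise against the mixture and still be higher in its few stromal-like cells. In the 7 collagen-defined BMAC cells of the fifth question, CXCL12 and LEPR stood above culture (ratios of 38.6 and 56.6). The marrow niche list did too (median log2 ratio 3.80).

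The other leading genes higher in culture had few or no BMAC counts. With no BMAC count stood STC2, a secreted glycoprotein hormone (354 CPM, at least 7983-fold), the keratin-binding FLG (313 CPM, at least 7056-fold), POSTN, a matrix protein of connective tissue (286 CPM, at least 6448-fold), EDIL3 (147 CPM, at least 3304-fold) and the fibroblast protease FAP (98.2 CPM, at least 2214-fold). CYR61 stood at 683 CPM, 15400-fold above its 3 BMAC counts (5270 to 74690), THBS2 at 370 CPM, 12510-fold above its 2 counts (3461 to 103300), and PENK, a precursor of opioid peptides, at 827 CPM with 5 BMAC counts. The leading genes lower in culture were those of blood cells, each with no cultured count. They were NKG7 of cytotoxic lymphocytes (271 ± 82.7 CPM in BMAC, at least 4552-fold), IGLL1 of B precursors (217 ± 92.4, at least 3413-fold), CD48 (204 ± 64.6, at least 3517-fold), KLRB1 (168 ± 87.7, at least 2875-fold), CD3D (135 ± 58.7, at least 2224-fold), HBG2 (141 ± 105, at least 2176-fold), PRTN3 of granule-forming precursors (132 ± 96.5, at least 2327-fold) and LCP1 (121 ± 42.3, at least 2161-fold).

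Each of the 3 consensus surface positives rose. NT5E was at 81.4 CPM against 2.14 ± 1.18 in BMAC (log2 fold change 5.41, SE 0.419, edgeR adjusted p = 1.46e-07), THY1 at 334 against 0.230 ± 0.179 (10.57, SE 0.345, 6.21e-11) and ENG at 260 against 20.4 ± 3.36 (3.73, SE 0.230, 1.42e-08). In camera the list passed with the preset correlation (adjusted p = 0.00564), and the adjusted p was 0.0947 with an estimated correlation. All 7 consensus negatives fell. CD34 fell by 6.34 on the log2 scale (0.133 against 12.5 ± 5.61 CPM, edgeR adjusted p = 1.45e-05), CD14 fell by 4.24 (0.877 against 18 ± 10.1 CPM, edgeR adjusted p = 0.00209) and ITGAM had no cultured count (at least 297-fold lower). Their camera adjusted p was 3.56e-05 with the preset and 0.0947 with an estimated correlation. LEPR rose by 2.50 (43.7 against 7.86 ± 3.43 CPM, SE 0.446, edgeR adjusted p = 0.000361). CXCL12 rose by 4.94 (394 against 12.1 ± 17.0 CPM, SE 1.40, edgeR adjusted p = 0.00913), a call that DESeq2 did not give (5.87, adjusted p = 0.0710). Of 14 other MSC surface markers 10 rose and 1 fell, with VCAM1 up by 7.10 and PDPN with no BMAC count (at least 38.7-fold), though DESeq2 gave PDPN a fold of 6.11 and an adjusted p of 0.127. The list's adjusted p was 0.0906 with an estimated correlation.

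Most matrix and contractile genes rose. All 24 extracellular matrix genes rose, with a median log2 fold change of 10.49 (camera adjusted p = 3.79e-14 with the preset, 0.0906 with an estimated correlation). Of 12 contractile cytoskeleton genes 11 rose and none fell, with a median of 7.11 (8.28e-08, and adjusted p = 0.0871 with an estimated correlation). Among them the actin-binding TAGLN was at 8003 CPM against 2.21 ± 0.971 in BMAC (log2 fold change 11.88), and CNN1 had no BMAC count (at least 907-fold). Of 12 marrow niche genes 10 rose and none fell, 1 of the rest falling when adjusted over the list alone, with the transcription factor PRRX1 (136.8 CPM, 2 BMAC counts, 4628-fold, interval 1281 to 38220) and VCAM1 leading (0.00211, and adjusted p = 0.262 with an estimated correlation). Chondrogenic genes rose in 6 of 7, led by HAPLN1 and COMP, 1 more falling when adjusted over the list alone, and the list had an adjusted p of 0.0871 with an estimated correlation. Osteogenic genes rose in 4 of 5, among them DLX5, or 5 adjusted over the list alone (adjusted p = 0.206 with an estimated correlation). Of 8 adipogenic genes 1 rose and 3 fell, with the fatty acid transporter CD36 at 192 ± 53.1 CPM in BMAC and 3 counts in culture. LPL fell by 4.68 (edgeR adjusted p = 0.0392), a call lost narrowly without replicate 1, 3 or 5 (adjusted p 0.0506, 0.0532 and 0.0526) while the fold stayed (-4.73, -4.585 and -4.565). The camera adjusted p of the adipogenic list was 0.551.

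Most glycolysis genes rose and most proliferation genes fell. Of 14 glycolysis genes 12 rose and none fell, with a median log2 fold change of 2.25 (camera adjusted p = 0.000115 with the preset, 0.206 with an estimated correlation). PKM, pyruvate kinase, rose by 3.50 and LDHA, lactate dehydrogenase A, by 3.35. Of 22 proliferation genes none rose and 14 fell, or 17 adjusted over the list alone, with a median of -1.69 (0.000113, and adjusted p = 0.309 with an estimated correlation). The replication licensing genes MCM2 fell by 2.74 and MCM5 fell by 2.60. The cell cycle markers gave 5 of 8 lower, or 6 adjusted over the list alone, with NUSAP1, which fell by 2.54, and MKI67 at 17 against 94.3 ± 21.8 CPM (adjusted p = 0.309 with an estimated correlation). Of 12 senescence and p53 targets 8 rose and 1 fell, among them IGFBP3, which also serves in growth factor binding (adjusted p = 0.0906 with an estimated correlation). All 7 MHC class II genes fell, with a median of -4.76. HLA-DRA fell by 6.04 (10.1 against 715 ± 227 CPM) and HLA-DPA1 fell by 5.47 (list adjusted p = 0.206 with an estimated correlation). Of 14 immediate early stress genes 6 rose and none fell, led by EGR1 (4.57) and IER3 (4.52), with a camera adjusted p of 0.0684.

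Among secreted factors, more growth factor and protease genes rose than fell, and more pro-inflammatory cytokine and chemokine genes fell than rose. Of 30 growth factors 20 rose and 5 fell, or 21 and 5 adjusted over the list alone, with VEGFC, a lymphatic growth factor, up by 9.67 and FGF2 at 29.6 CPM with 3 BMAC counts, 667-fold (interval 228 to 3237). The list's adjusted p was 0.132 with an estimated correlation. Of 27 matrix proteases and inhibitors 17 rose and 7 fell, among them the gelatinase MMP2 (9.98), with an adjusted p of 0.307 with an estimated correlation. Of 16 pro-inflammatory cytokines 1 rose, IL6 (7.86), and 12 fell, or 2 and 12 adjusted over the list alone. LTB was at 347 ± 250 CPM in BMAC and 0.172 in culture, and the list had an adjusted p of 0.206 with an estimated correlation. Of 11 chemokines 1 rose and 6 fell, led by CCL4 with no cultured count (at least 836-fold lower) and CCL5, which fell by 9.81 (adjusted p = 0.217 with an estimated correlation). Of 18 anti-inflammatory factors 7 rose and 7 fell, with the prostaglandin E synthase PTGES up by 9.57 and ARG1 at no cultured count, and the camera adjusted p was 0.750.

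All 10 stromal markers rose, COL1A2 by 12.73, as did 4 of 5 smooth muscle and pericyte markers, ACTA2 by 8.77, with 1 lower. All 10 erythroid markers fell (AHSP fell by 13.05 and HBA1 fell by 12.99), as did all 8 T markers, all 7 B markers, 7 of 8 NK markers (8 adjusted over the list alone) and 10 of 11 granulocyte precursor markers. For each of these lists the adjusted p was 0.206 with an estimated correlation, as it was for neutrophil markers, of which 6 of 7 fell and 1 rose. Of 9 monocyte markers 8 fell and 1 rose (LYZ fell by 12.81), and all 5 conventional dendritic markers fell (adjusted p = 0.217 with an estimated correlation for both). All 6 eosinophil, basophil and mast markers, 5 of 7 plasmacytoid dendritic markers and 4 of 6 plasma markers fell, with 1 rise in each of the last 2 lists (adjusted p = 0.309 with an estimated correlation). All 5 macrophage markers and 7 of 10 haematopoietic stem and progenitor markers fell, the latter with 2 rises and 8 falls adjusted over the list alone (adjusted p = 0.306 with an estimated correlation). All 7 megakaryocyte markers fell (adjusted p = 0.305 with an estimated correlation). B precursor markers fell in 5 of 9 and rose in 1 (adjusted p = 0.423 with an estimated correlation). Endothelial markers gave 1 rise, TEK, and 1 fall, PLVAP, of 3 (camera adjusted p = 0.747). The single rises of the neutrophil, monocyte, B precursor and endothelial lists were each lost in some other settings, and the endothelial falls became 2 or 3 in others. The 1 osteoblast marker tested rose when adjusted over the list alone, and without replicate 5 also when adjusted over all genes, and 4 rose with no filter on low counts. No adipocyte marker passed the filter. Of the 38 lists tested with camera, none passed with an estimated correlation, the smallest adjusted p being 0.0871.

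**Figure D3:**
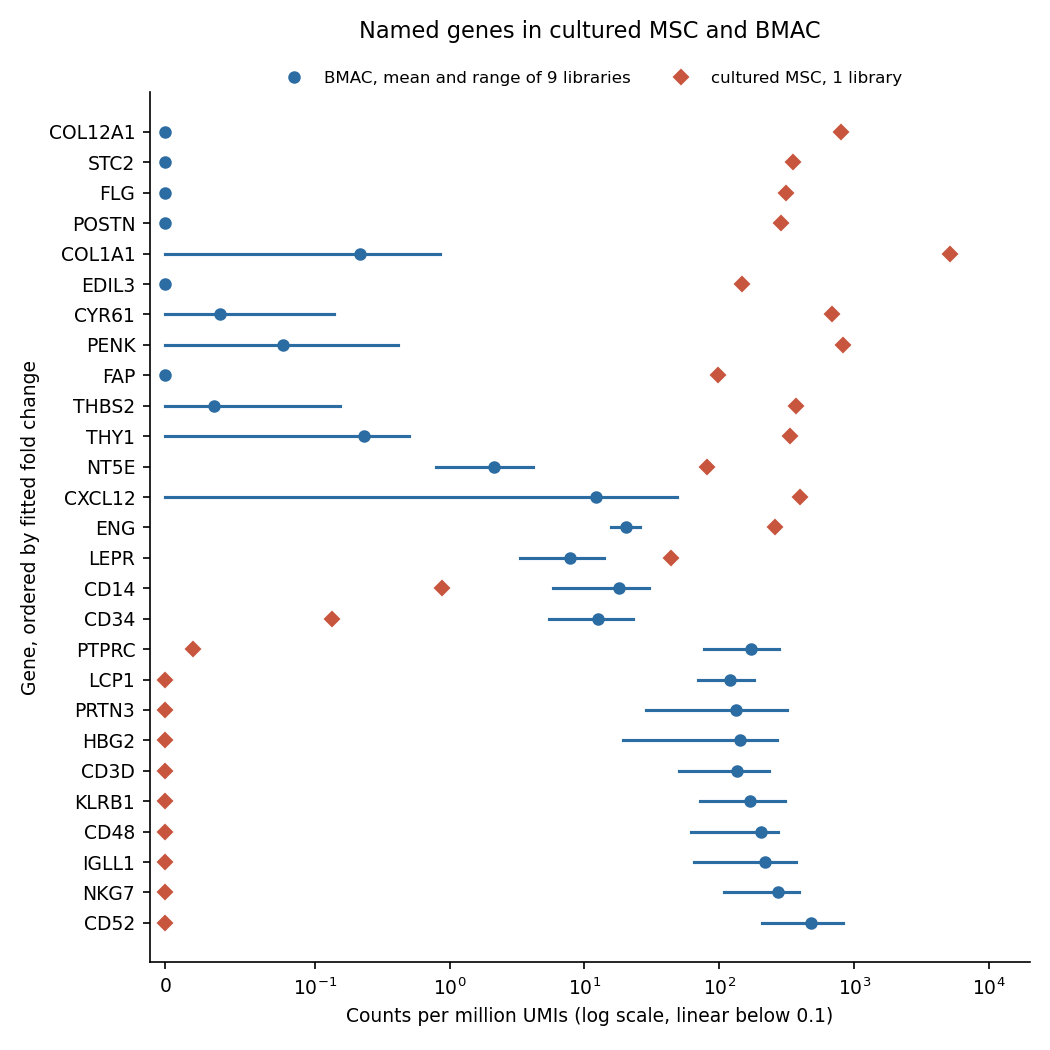
Named genes in CPM (x axis, logarithmic above 0.1 and linear below) for the cultured library (diamonds) and for BMAC (circles at the mean and lines over the range of 9 libraries), with genes on the y axis ordered by fitted fold change. Genes of blood cells such as CD52 sit at 0 in culture, and matrix genes such as COL12A1 sit at 0 in BMAC.

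The fourth question was which classes of the concentrate carry transcripts of secreted and matrix-active factors. Monocyte-like cells led: 34 of the 47 list genes tested were higher there than in the log-scale mean of the other 9 classes, and 6 lower. SERPINA1, the main inhibitor of neutrophil elastase, was at 467.5 ± 131 CPM in monocyte-like cells (SD, n = 9), a log2 fold change of 7.60 (SE 0.171, edgeR adjusted p = 2.04e-57). T and NK-like cells held IL32 at 804 ± 206 CPM (6.60, SE 0.128, adjusted p = 5.17e-65) and the chemokine CCL5 at 699.7 ± 276 CPM (5.86, SE 0.160, adjusted p = 1.58e-53). Erythroid-like cells were lower for 31 of the 47 genes and higher for 4, among them the protease CTSL at 102 ± 25.3 CPM (7.36, SE 0.248, edgeR adjusted p = 1.23e-39). Of these 4, HMOX1 (2.21 against 9.76 CPM) and LGALS9 (37.65 against 61.35 CPM) stood below the mean CPM of the other classes. The fit compares log-scale means after TMM normalization, whereas these CPM values are not TMM-scaled. Which difference gives these calls was not tested. Conventional dendritic-like cells were higher for 27 and lower for 6, T and NK-like for 20 and 12, plasma-like for 20 and 9, plasmacytoid dendritic-like for 13 and 7, B-like for 12 and 13, haematopoietic stem and progenitor-like for 12 and 13, granulocyte precursor-like for 12 and 9, and B precursor-like for 6 and 24. Over all 470 pairs of gene and class 160 were higher and 130 lower, and without a filter on low counts 279 were higher and 134 lower of 1170 pairs.

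The 11 anti-inflammatory factors gave 45 higher and 26 lower pairs, or 48 and 26 adjusted over the list alone. The decoy receptor IL1R2 was at 80.4 ± 75.8 CPM in monocyte-like cells (5.41), with HMOX1 (4.88) and TNFRSF1B (3.98) beside it, and HMOX1 was also higher in plasma-like cells (3.59, n = 5). The 9 pro-inflammatory cytokines gave 33 higher and 29 lower, or 33 and 30 adjusted over the list alone. LTB was at 1671 ± 434 CPM in B-like cells (4.77) and 1090 ± 674 in T and NK-like cells (4.13). IL1B, the inflammasome cytokine, was highest among the named classes in haematopoietic stem and progenitor-like cells at 58.6 ± 21.6 CPM (4.58, SE 0.246, n = 8, edgeR adjusted p = 8.42e-30), above monocyte-like cells at 17.4 ± 7.97 CPM (2.53) and conventional dendritic-like cells at 13.6 ± 12.5 CPM (1.92). In T and NK-like cells IL1B had 2 counts.

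The 10 growth factors gave 33 higher and 24 lower pairs, or 37 and 24 adjusted over the list alone. CTGF, a matricellular protein, was at 49.7 ± 43.7 CPM in B precursor-like cells (6.17, n = 8), a call DESeq2 did not give (5.26, adjusted p = 0.0835). HGF was at 78.9 ± 28.5 CPM in granulocyte precursor-like cells (6.04, n = 7) and MDK at 172 ± 41.3 CPM in plasma-like cells (5.10, n = 5). CTGF in plasma-like cells (4.68) was not called by DESeq2 (4.25, adjusted p = 0.334), and over all plasma-like cells it fell from 10.4 to 0.631 CPM without the collagen-defined cells that cluster there. TGFB1 was higher in monocyte-like cells (166 ± 44.6 CPM, 2.14), T and NK-like cells (116 ± 53.9 CPM, 1.93), conventional dendritic-like cells (0.81), plasmacytoid dendritic-like cells (0.83) and B-like cells (0.68), and lower in erythroid-like cells (-3.64), B precursor-like cells (-1.89) and granulocyte precursor-like cells (-1.18). In B-like cells TGFB1 was at 59 CPM, below the mean of 66 CPM in the other classes, so that call rests on the log-scale mean. The B-like call was lost without replicate 2 (0.38), without the library block (0.66), with no filter on low counts (0.50) and without the cells of highest doublet score (0.44). The granulocyte precursor-like call was lost at resolution 0.5 (-0.01) and without those high-scoring cells (-0.41).

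The 12 matrix proteases and inhibitors gave 38 higher and 42 lower pairs, or 39 and 43 adjusted over the list alone. CST3, a cathepsin inhibitor, was at 4091 ± 725 CPM in conventional dendritic-like cells (4.91, n = 8), and CST7 at 307 ± 104 CPM in granulocyte precursor-like cells (4.55, n = 7). TIMP1, an inhibitor of matrix metalloproteinases, was higher in monocyte-like cells (257 ± 43.7 CPM, 3.26), conventional dendritic-like cells (188 ± 48.4 CPM, 2.56), plasma-like cells (1.502) and T and NK-like cells (1.17). It was lower in B precursor-like (-2.80), erythroid-like (-2.05), B-like (-1.87), granulocyte precursor-like (-1.05) and plasmacytoid dendritic-like cells (-0.89). The granulocyte precursor-like value turned to 0.89 at resolution 0.5 and to 0.61 without the cells of highest doublet score, where that class took in more cells. Its call was lost without replicate 7 (-0.87) and in the 6 libraries whose names share letters (-0.83). The plasmacytoid dendritic-like call was lost in those 6 libraries (-0.64) and with doublet calls kept (-0.24). The 5 chemokines gave 11 higher and 9 lower, or 12 and 10 adjusted over the list alone. The 11 became 4 without replicate 2, and 31 with no filter on low counts, where more genes were tested. Leading pairs were XCL2 (5.87), CCL5 and CCL4 (4.68) in T and NK-like cells and CXCL16 in monocyte-like cells (4.73). Of the genes named in advance, IL1RN, VEGFA, IGF1 and MMP9 did not pass the filter on low counts. In the fit without that filter IL1RN was at 22.1 ± 14.8 CPM in monocyte-like and 20.01 ± 14.2 in conventional dendritic-like cells, VEGFA at 12.2 ± 9.26 in monocyte-like and 9.40 ± 7.30 in erythroid-like cells, and IGF1 at 75.4 ± 44.0 CPM in plasma-like cells (7.17, n = 5), while MMP9 was called in no class.

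**Figure D4:**
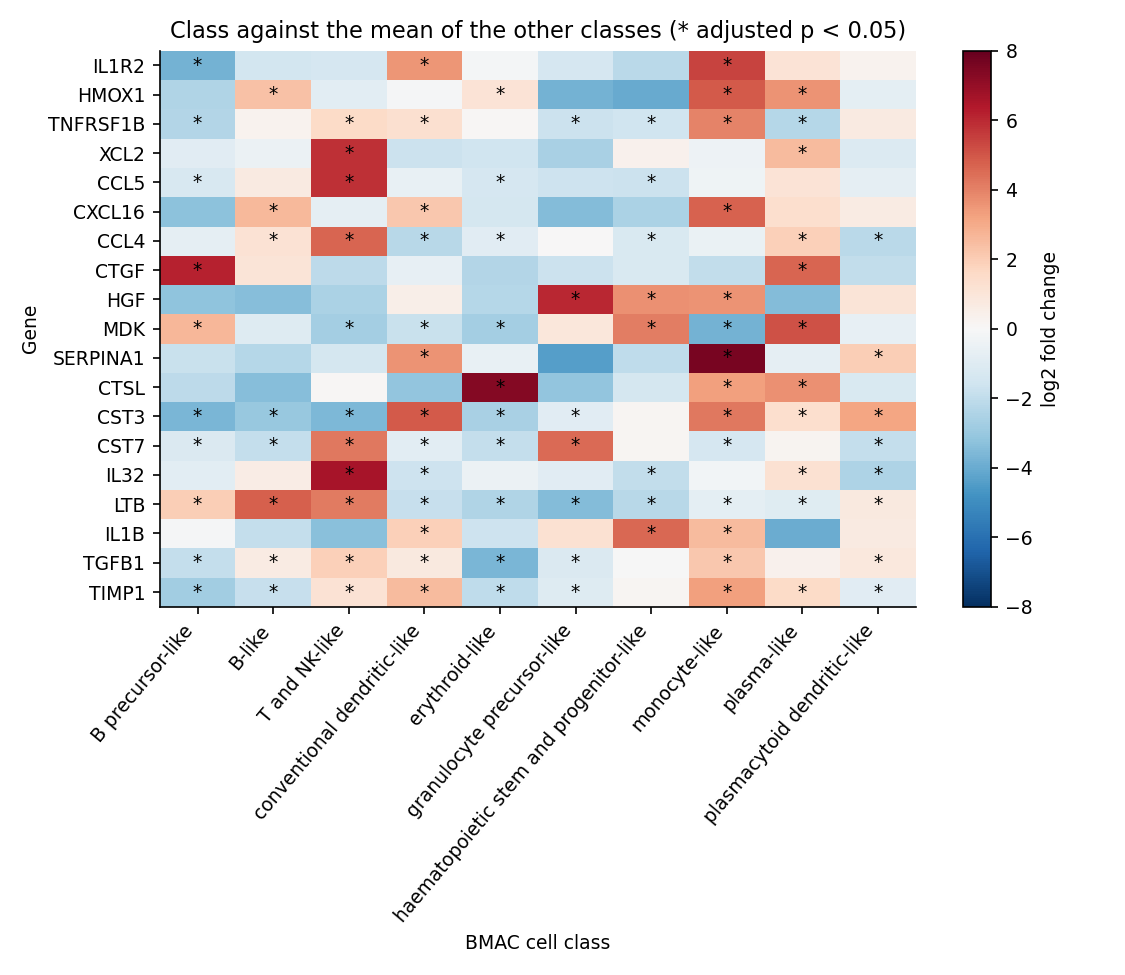
Log2 fold change (colour, red for higher and blue for lower) of named secreted-factor genes (y axis) in each of the 10 named BMAC classes (x axis) against the log-scale mean of the other classes, with an asterisk where the adjusted p passed 0.05. SERPINA1 reached 7.60 in monocyte-like cells, IL32 6.60 in T and NK-like cells and IL1B 4.58 in haematopoietic stem and progenitor-like cells.

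The fifth question was how the few stromal-like cells found in BMAC compare with cultured MSC. No stromal-like cluster was found, so the 7 collagen-defined cells at full depth were used, with 61531 UMIs from 4 libraries. Niche genes stood far higher in them: CXCL12 was at 15160 CPM from 933 counts against 393 CPM in culture, a ratio of 38.6 (95% counting interval 36.1 to 41.2), and LEPR at 2470 against 43.7 CPM, a ratio of 56.6 (47.7 to 66.7). COL1A1 was 24.2-fold lower (14.1 to 45.4), COL1A2 6.09-fold lower (4.52 to 8.42) and the contractile gene TAGLN 15.9-fold lower (11.2 to 23.4). COL3A1 (ratio 0.701, 0.434 to 1.07) and the proteoglycan genes DCN (0.983, 0.730 to 1.30) and LUM (1.01, 0.700 to 1.41) could not be told from the cultured level. The 7 cells were selected on COL1A1, COL1A2, COL3A1, DCN and LUM, so the levels of these 5 genes are partly set by the selection. In an edgeR test on sums per library, added after the data were seen, 25 of 302 genes were higher in the BMAC cells and 38 lower. CXCL12 (4.85, SE 1.37, adjusted p = 0.0182), LEPR (5.51, SE 1.33, adjusted p = 0.00964), COL1A1 (-4.935, adjusted p = 0.00197), COL1A2 (-2.86, adjusted p = 0.0157) and TAGLN (-4.385, adjusted p = 0.00197) were called by edgeR. COL3A1 (-0.78), DCN (-0.55) and LUM (-0.41) were not, and NT5E, THY1 and ENG did not pass its filter. The CXCL12 call was lost without replicate 2 (4.97, SE 2.14, edgeR adjusted p = 0.0869) and without replicate 8 (5.10, SE 1.74, adjusted p = 0.0888), where the fold did not shrink and the SE grew. The COL1A2 call was lost without replicate 2, 3 or 8 (-2.685, -2.69 and -2.60), while those of LEPR, COL1A1 and TAGLN were kept. Replicates 1 and 2 moved the pooled ratios most: without replicate 1 the ratio was 66.3 for CXCL12 and 128 for LEPR, with COL1A1 9.64-fold lower, and without replicate 2 these were 29.2, 31.2 and 62.9-fold. The TAGLN ratio was 0.127 without replicate 1 and 0.0356 without replicate 2. One of the 7 cells was mostly haemoglobin (4101 UMIs). Another carried 44 counts of the plasma cell gene MZB1 and held 26239 of the 61531 UMIs, so it weighs heavily in the pooled ratios. In the 5 cells left without these, the ratios were 66.95 for CXCL12 and 105 for LEPR. There COL1A1 was 13.3-fold and TAGLN 8.6-fold lower.

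The highest ratios belonged to genes barely seen in culture. The ferroxidase CP had 70 counts in the 7 cells and none in culture (at least 19920-fold), and SPARCL1 33 counts and none (at least 9389-fold). CHL1 and CRH, the latter encoding corticotropin-releasing hormone, each had 49 counts against 1 cultured count (41820-fold, 7163 to 1685000). HP had 52 counts against 2 (22190-fold, 5842 to 188100), transferrin gene TF 70 against 5 (11950-fold), and lipoprotein lipase gene LPL 32 against 3 (9104-fold, 2848 to 46470). HBA2 (4702-fold) came largely from the haemoglobin-rich cell. The lowest ratios had no count in the 7 cells: SERPINE2 (at least 43.8-fold lower), PENK (at least 17.0-fold), COL12A1 (at least 16.4-fold), CYR61 (at least 14-fold), COL8A1 (at least 12.4-fold), CTHRC1 (at least 11.9-fold), MAP1B (at least 10.9-fold) and ITGA11 (at least 10.5-fold).

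By list, the examples below were chosen after their values were seen. The marrow niche list had a median log2 ratio of 3.80, or 3.67 with genes at 0 set to their bound, the 100th percentile of 10000 random lists, with 10 of 11 genes above 1, among them KITLG (18.6, 7.95 to 37.0), EBF3 (10.9, 4.96 to 20.8) and VCAM1 (7.42, 5.72 to 9.47). Adipogenic genes had a median of 6.31 (6.23 at the bound, 100th percentile, 7 measured), MHC class II genes 4.56 (4.48, percentile 99.9), led by HLA-DRA (45.1) and CD74 (30.3), anti-inflammatory factors 2.85 (2.63, percentile 99.98), immediate early stress genes 1.37 (1.35, percentile 99.8), growth factors 1.06 (0.98, percentile 99.6) and osteogenic genes 0.89 (0.57, percentile 79.5). Without replicate 1, which held 3 of the 7 cells, the immediate early median turned to -1.855, and the medians were 4.97 for niche, 7.57 for adipogenic, 2.79 for growth factor, 1.91 for osteogenic, -1.99 for glycolysis, -2.49 for chondrogenic and -1.19 for senescence genes. Without it the erythroid marker median was 5.605 and that of smooth muscle markers -2.945. Without replicate 2 the adipogenic median was 3.125 and that of matrix proteases and inhibitors -2.65. The osteogenic median was 4.08 without replicate 3, 7.09 without replicate 8 and 3.53 in the collagen-defined cells after thinning. In the 8 cells with LEPR and CXCL12 the median was 2.005 for proliferation, 4.14 for anti-inflammatory, 5.79 for MHC class II, 3.46 for osteogenic and -1.58 for senescence genes. Of these 8 cells, 6 lay in the plasma-like cluster, 1 was conventional dendritic-like and 1 lay in cluster 5. They held 77296 UMIs, against 57430 in the 6 cells with over 10 CXCL12 UMIs. The other cells may carry these shifts, which was not tested. Extracellular matrix genes had a median of -2.16 (-2.04 at the bound, percentile 0.01), with 18 of 24 below 1, among them FN1 (24.4-fold lower) and SPARC (8.21-fold lower). Contractile genes had -3.01 (-3.09, percentile 0.14), glycolysis genes -3.10 (-2.88, percentile 0.01) with GAPDH 19-fold and LDHA 12-fold lower, senescence and p53 targets -2.63 (-1.31, percentile 0.22) and chondrogenic genes -3.93 (-1.35, percentile 0). Matrix proteases and inhibitors (-1.08, -1.64 at the bound, percentile 4.46), other MSC surface markers (-0.70, -0.76, percentile 25.7), consensus surface positives (-1.54, -1.68, percentile 5.18), proliferation genes (-1.16, -1.08, percentile 5.11) and stromal markers (-0.24, -0.27, percentile 80.4) lay within or near the range of random lists. Smooth muscle markers had -3.97 (-3.99, percentile 0.64), plasma markers 10.79 (10.80, percentile 99.9) and erythroid markers 9.44 (percentile 99.98), or 8.39 with haemoglobin genes left out of the totals, 8.25 in the cells with over 10 CXCL12 UMIs, 7.44 in the 5 of these with under 10 MZB1 UMIs and 8.39 without replicate 8. Of the plasma markers, 3 passed the mean CPM minimum in the 7 cells and 0 in the 5 cells with under 10 MZB1 UMIs. The cell with 44 MZB1 counts may therefore carry the plasma median. The remaining lists had fewer than 3 genes above the minimum.

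The consensus surface genes were thinly covered: NT5E had 3 counts (ratio 0.600, 0.124 to 1.75), ENG 5 (0.313, 0.102 to 0.731) and THY1 1, a 20.6-fold lower level (3.69 to 812). In the 5 cells with over 10 CXCL12 and under 10 MZB1 UMIs (31191 UMIs, chosen after the values were seen) CXCL12 stood at a ratio of 66.9 (62.4 to 71.8), LEPR at 105 (88.1 to 124), COL1A1 13.3-fold lower (7.60 to 25.7) and TAGLN 8.60-fold lower (5.99 to 12.8). Since these cells were chosen by CXCL12, its ratio in them is no separate test. DCN was then 1.47 (1.04 to 2.02), LUM 1.41 (0.902 to 2.10) and COL3A1 1.25 (0.753 to 1.95). CHRDL1 (2862-fold) took the place of HBA2 among their 8 highest ratios.

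**Figure D5:**
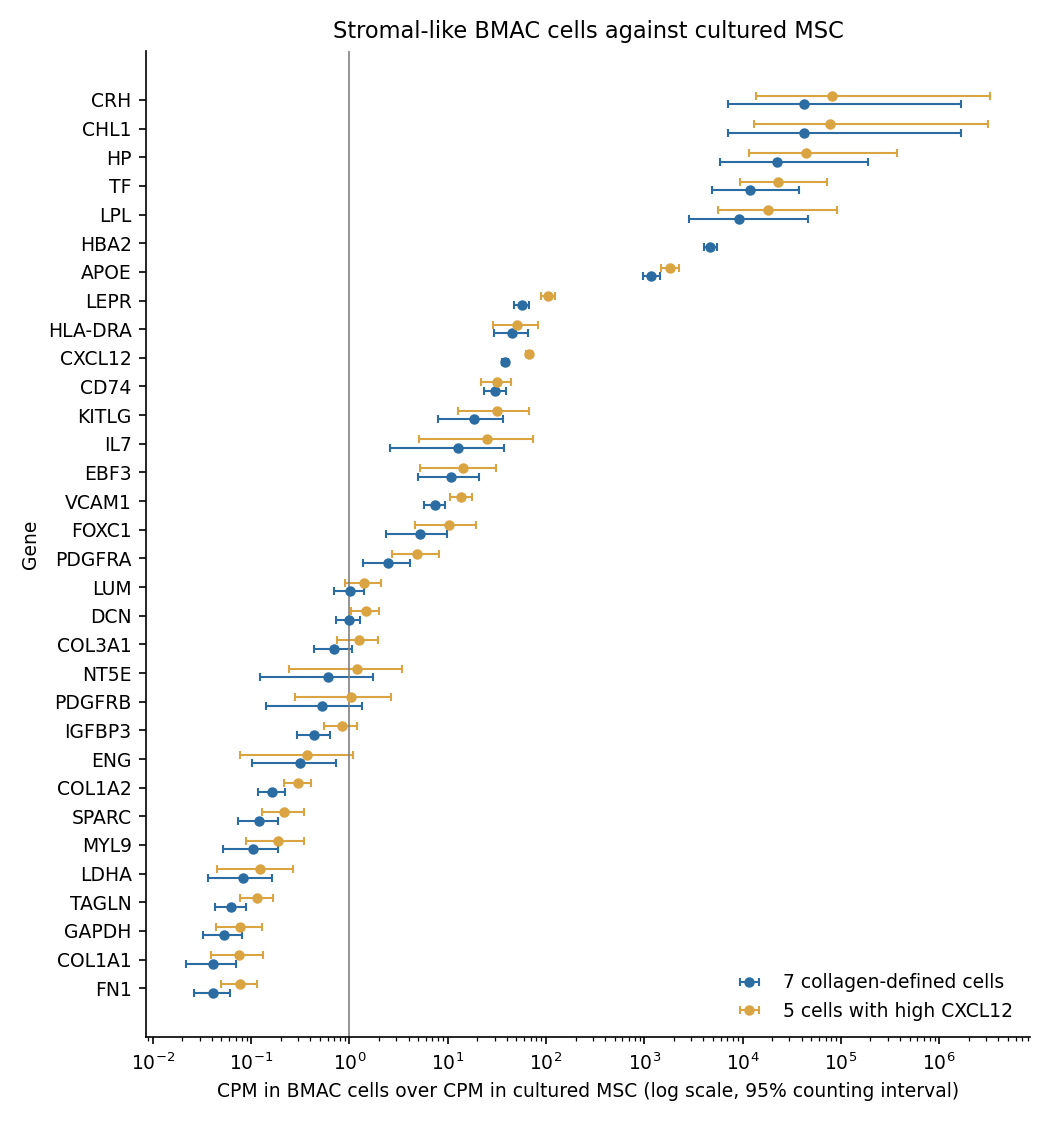
Ratio of CPM in the 7 collagen-defined BMAC cells (blue) and in the 5 with high CXCL12 (ochre) to CPM in cultured MSC (x axis, log scale, bars the 95% counting interval) for named and example genes with at least 3 UMIs in the 7 cells and at least 1 in culture (y axis). CXCL12 (38.6) and LEPR (56.6) lie above 1, COL1A1 and TAGLN lie below it, and the intervals of DCN and LUM in the 7 cells include 1.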

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

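Of the tests here, the haemoglobin share of T and NK-like cells in replicate 7, the median shares, the range without replicate 1 and the UMI minimum common to all BMAC libraries were chosen only after the results were seen. In 95 groups of 9 BMAC values, Dixon's gap test picked out 8 in which 1 library stood apart, and chance gives about 1 in 20.

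Replicate 2 stood highest in conventional dendritic-like cells, with 7.61% of cells against 3.99% in the next library, and in JCHAIN, the immunoglobulin joining chain gene, with 604 CPM over all its cells against 257. Replicate 6 stood highest in cluster 10, led by RETN, MPO and LYZ, with 7.99% against 4.31%. It was also highest in MS4A3, a gene of granulocyte precursors and basophils, with 33.1 CPM against 17.4, and in cells with NGFR and without PTPRC, with 0.170% against 0.0855%. That is 2 cells against 1 at 1000 UMIs, and at full depth replicate 3 was higher, with 0.513% against 0.425%, so this rests on single cells. Replicate 8 stood highest in LTB, with 933 CPM against 524. Replicate 7 stood highest in cluster 16, led by AK1, AKR1C3 and HBQ1, with 5.84% against 2.03%, and in cluster 24, which mixes red cell and T cell genes, with 5.13% against 0.348%.

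Replicates 7 and 9 also held most of the barcodes with fewer than 200 genes, 24.8% and 32.4% of their deposited barcodes, against 9.75% in replicate 1 and at most 2.65% in the other 6 libraries. Free haemoglobin RNA from broken red cells is a candidate source in replicate 7, since haemoglobin made up 12.8% of counts in its T and NK-like cells, against at most 1.41% in the libraries other than 7 and 9. The median cell there held 2.06%, against at most 0.858%, so part of the cells carries much of the pooled share. In replicate 9 the pooled share was 1.26%, within the range chosen in advance, but the top of that range is replicate 1, which held such barcodes itself. The other 6 libraries reached at most 0.388%, so that range was the wrong standard, and free RNA stays open in replicate 9. A lower UMI minimum in these libraries was not the whole cause: counting only barcodes above the common minimum of 3363 UMIs, the share with fewer than 200 genes was 7.04% in replicate 7 and 9.68% in replicate 9, close to the 7.90% of replicate 1 and above the other 6 libraries, which had at most 1.96%. Replicates 1, 7 and 9 also had the highest shares of erythroid-like cells (30.7%, 33.1% and 27.7%), with 19.4% in replicate 3 as the next. Whether those shares and the low-gene barcodes have a common source was not tested. What separates replicate 9 stays open, and no biological explanation was tested, since the labels name no difference between the BMAC samples.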

How the results depend on the processing

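Alternatives chosen after the data were seen were removal of the 5% of cells with the highest doublet scores, no minimum of genes per cell, the common UMI minimum, fits without the collagen-defined cells, the other choices of stromal-like cells, and edgeR on their sums per library. The rest were fixed in advance. The count of genes called between cultured MSC and BMAC stayed within 1.5 times in all 32 comparisons of settings, from 3515 to 3774 higher and 3251 to 3475 lower when each BMAC library was left out. One of the settings, at least 1000 UMIs per cell, removed no cell, so its counts could not move. DESeq2 gave 3531 higher and 3577 lower, and the 6 libraries of one possible batch 3679 and 3494. Named genes in that comparison kept direction and call in 1447 cases, and 5 lost the call, for CXCL12, LPL and PDPN as given in the report. The counts per gene list stayed within 1.5 times in 1238 cases and moved in 42, most of them counts of 0 or 1 as reported. The single rise became 0 for neutrophil markers with DESeq2, in the 6 libraries of one possible batch and without replicate 3, 5, 6, 8 or 9. It became 0 for B precursor markers with DESeq2, with haemoglobin genes left out and without replicate 1, 3, 4, 5 or 6, and for monocyte markers without replicate 1, 5, 8 or 9. For endothelial markers the rise became 0 with haemoglobin genes left out, and the single fall became 2 there, in those 6 libraries, with no gene minimum and without replicate 4, 5, 8 or 9, and 3 with no filter on low counts.

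Class shares stayed within 1 SD in 94 cases and moved in 6. Granulocyte precursor-like cells moved from 1.69% to 5.36% at resolution 0.5, 4.455% with 1000 variable genes, 4.34% with the 5% highest doublet scores removed, 3.44% with no gene minimum and 4.305% at the common UMI minimum. At that minimum B-like cells moved to 2.37%. The cause was not tested. For the definitions, depth sets the counts. The share with LEPR and without PTPRC (0.363% at 1000 UMIs) was 2.08% without thinning, 0.133% at 500 UMIs, 0.628% at 2000 UMIs and 0.0393% when 2 UMIs were required. The NGFR share was 0.162% without thinning and 0.142% at 2000 UMIs, and THY1 with VCAM1 was 0.00644% without thinning. The LEPR share minus the collagen share passed the exact permutation test without thinning (2.02, adjusted p = 0.0312) and at 2000 UMIs (0.5875, adjusted p = 0.0312), and the other settings left the definitions on the same side.

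Across classes, 279 pairs were higher without a filter on low counts, where more genes were tested. By list, the chemokine count of 11 became 31 without that filter and 4 without replicate 2, whose cause was not tested. Leaving out each library gave 141 to 166 higher and 105 to 131 lower, and the fit with no replicate block gave 155 higher and 119 lower. With class names permuted within libraries in 25 fits, the real one included, only 1 gave as many higher pairs (160, the highest other 16). Only 1 gave as many lower pairs (130, the highest other 5). The classes come from clustering the same cells, so shuffled names were bound to give fewer calls even with the list genes left out of the clustering. These fits therefore cannot decide whether chance played a part. Of named pairs 896 kept direction and call, 12 lost the call, 3 gained it and 2 reversed: TIMP1 in granulocyte precursor-like cells was 0.89 at resolution 0.5 and 0.61 with the 5% highest doublet scores removed, both settings in which this class took in more cells.

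The CXCL12 ratio of stromal-like cells to culture (38.6) was 41.3 in cells with over 10 CXCL12 UMIs, 66.9 in those also under 10 MZB1 UMIs, 30.8 in cells with LEPR and CXCL12, 34.0 in the collagen-defined cells after thinning, and 29.2 to 66.3 with each library left out. The choices by CXCL12 UMIs, and that of cells with LEPR and CXCL12, select on CXCL12 itself and so do not test its ratio. Among the cells with LEPR and CXCL12, 1 was conventional dendritic-like and 1 lay in cluster 5. With edgeR on sums per library the CXCL12 ratio was 28.9 (adjusted p = 0.0182). The median of immediate early stress genes turned to -1.855 without replicate 1, which held 3 of the 7 cells. With 61531 UMIs over 7 cells, 1 UMI is worth 16.3 CPM, which limits any statement on weakly expressed genes.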

Other observations

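The tests and levels of markers by class below, the seen and expected counts, the MZB1 counts and the comparison of source with culture were chosen only after the results were seen. In cluster 5 no marker list used for naming had a mean log2 fold above 0 over the other cells, and it stays unnamed. Of genes picked after the values were seen, KLF1 was at 314 CPM there, against 303 in erythroid-like and 2.75 in T and NK-like cells, and TFRC at 536, against 447.5 and 10.75. LEPR was at 24.6 ± 8.31 CPM there (SD, n = 9) against 4.42 ± 3.26 in the other BMAC cells, higher in 9 of 9 libraries. ENG was at 72.4 ± 8.53 against 10.25 ± 1.64 CPM, also higher in 9 of 9. Cluster 5 was singled out by its LEPR cells, and neither gene was kept out of the clustering, so no p is given for them. IL1B was at 152 ± 39.7 CPM in cluster 13, which also expressed GATA2 (139 CPM) and the mast cell tryptase TPSAB1 (62.7 CPM), against 6.91 ± 2.69 in other cells, higher in 7 of 7 libraries. IL1B is among the genes by which cluster 13 was noticed, so no p is given for it. NGFR was at 24.8 ± 23.2 CPM in plasmacytoid dendritic-like cells against 0.349 ± 0.350, higher in 5 of 7 libraries. It failed the correction (two-sided exact sign-flip permutation test, p = 0.0625, adjusted p = 0.0625 over 4 tests). The correction over 4 tests does not cover the choice of these pairs of gene and class after the values were seen.

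LEPR in cluster 5 was weighed against 3 technical sources. RNA carried over from the cultured library would bring far more TAGLN than LEPR, but TAGLN had 0.0410 counts per LEPR count (95% interval 0.0209 to 0.0726) against 183 in culture. Free RNA of the stromal-like BMAC cells would bring CXCL12, which had 0.0205 counts per LEPR count (upper bound 0.0451) against 6.14 in those cells. Reads of LEPROT, whose annotated span overlaps that of LEPR on the same strand (chromosome 1, 65420587 to 65436007), would keep a fixed ratio, but LEPR per LEPROT was 4.88 times that of T and NK-like cells (2.92 to 8.16). These values argue against each of the 3, and the source of LEPR in cluster 5 stays open, since no test of a biological explanation was run.

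The 6 collagen-defined BMAC cells with over 10 CXCL12 UMIs carried few counts of NT5E, THY1 and ENG, 9 in all. Too few UMIs per cell would leave the counts at the cultured level within the error, but 38.8 were expected there, and seen over expected was 0.232 (95% interval 0.106 to 0.441). In the 5 of them with under 10 MZB1 UMIs it was 0.333 (0.134 to 0.685), with THY1 10.4-fold lower than in culture (1.87 to 412, from 1 count), NT5E at a ratio of 1.18 (0.244 to 3.46) and ENG at 0.371 (0.0765 to 1.08), so the shortfall is not shown there for NT5E or ENG alone. Doublets with the plasma-like cells they cluster with would bring MZB1, which only 0.621% of the other cells of that cluster lacked, but 5 of the 6 had no MZB1 count (0.0373 expected), which argues against doublets in those 5 and leaves the cell with 44 counts open. Whether donor, supplier, library or culture separates them from cultured MSC cannot be told apart, because there was 1 cultured library.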
